A study of Mus musculus with 6 samples.

How the data were processed

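RNA from parotid salivary gland was measured in 6 mouse samples, 3 untreated and 3 irradiated, with libraries made from total RNA by a strand-specific kit, per the labels. The groups were taken from the treatment characteristic of each sample. The protocol text naming a radiation dose of 5 Gy stands on all 6 samples, untreated ones included, and was applied here to the irradiated group alone. The time between irradiation and tissue collection was not given in the labels. The names of the 3 irradiated tables carry a mark, D5, that may stand for a day; the labels do not explain it and it was not used. The labels do not say that each sample came from a separate mouse, so p-values measure the spread between these samples.

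The deposited values are whole-number read counts per Ensembl mouse gene, one table per sample. Base calling with bcl2fastq, alignment software HISAT2, counting software HTSeq and the genome build mm10 are listed in the submitters' processing notes. Their versions, the annotation release, the strand setting of the counting and any trimming were not given in the sources used here. Because of this, antisense and overlapping genes cannot be separated with certainty. Reads that aligned to more than 1 place stood in a row of their own (13.3% to 18.4% of all reads per library), so members of near-identical families such as amylases, proline-rich proteins and secretoglobins are uncertain. Rows naming no gene held 32.4% to 40.7% of all reads per library and were left out of library sizes and tests.

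Each table listed 52636 genes, of which 52403 matched a symbol in an annotation of the build mm10 and 233 did not. Coordinates, transcript lengths and GC content came from the same annotation. Counts in genes ranged from 7108359 to 15036193 per library. Libraries differed from each other far beyond sampling noise, with a chi-square per degree of freedom of at least 13.7 for any pair. That lowest value was for untreated replicate 2 against irradiated replicate 3, a pair across the groups. Within a group the lowest was 15.06, for untreated replicates 2 and 3. The chi-square served to look for duplicated libraries and does not rank their likeness. By correlation, untreated replicate 2 and irradiated replicate 3 stood at 0.9497. The lowest correlation within a group was 0.9544, for irradiated replicates 2 and 3. Other pairs across the groups reached 0.9626, for untreated replicate 1 and irradiated replicate 1, so the ranges overlapped.

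The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) with robust shrinkage, TMM normalisation and a filter on low counts (filterByExpr, minimum count 10), which kept 12885 genes. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Levels are given as CPM, counts scaled by library size and TMM factor. Values are mean ± SD over the 3 libraries of a group, and fold changes are irradiated over untreated, with the standard error (SE).

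Before the data were examined 42 gene lists were fixed. One of them, of sex-linked genes, served only as a check of the libraries and was not tested, and the other 41 covered DNA damage, gland function, metabolism, other cell types and sample quality. These were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry were run beside it. With the estimated correlation, 0 of the 41 lists passed, the lowest adjusted p was 0.0948, for the p53 targets, and 3 lists had an unadjusted p under 0.05. Fry's adjusted p passed for 3 lists by one-way change, the p53 targets, ribosomal proteins and peroxisomes, and for 13 lists by change in either direction. Neither compares a list with other genes. The SE over members beside a list's median is the SD of the members' log2 fold changes over the square root of their number. It is the error of a mean over genes taken as independent, not of the median, and does not measure the spread between samples.

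Genes are named by a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and no overlap between the groups, leaving out predicted genes and antigen receptor segments. It adds up to 4 called members of each list with the smallest p, or the 2 most abundant members where none was called, the 5 most abundant genes, and Cdkn1a, Mdm2, Ccng1, Aqp5, Amy1, Bpifa2, Slc12a2 and Mki67. This gave 92 genes, of which some are not reported here.

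The procedure was tested on simulated counts for these 12885 genes, with the libraries' own means and sizes and 200 changed genes in each of 5 runs. Of genes changed 1.5-fold, 8.06% were called, of those changed 2-fold 64.8%, and of those changed 4-fold 87.3%. Unchanged genes made up 10.7% of the calls, above the nominal share. Camera with the preset correlation called 0 unchanged lists in 5 runs of simulated counts, which hold no correlation between genes.

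The alternatives tried were DESeq2's size factors, library totals alone, library sizes without the 20 most abundant genes, no count filter, a minimum mean of 1 CPM, no robust shrinkage, DESeq2 1.42.0, limma-voom, a replicate term, the other list tests, and leaving out each library in turn. A correction for transcript length and GC content was added after seeing the data.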

Results

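The parotid gland is a salivary gland made largely of acinar cells, which secrete digestive enzymes. RNA was sequenced from parotid glands of FVB mice, an inbred laboratory strain, aged 28 days. The untreated group held 3 samples, and the irradiated group held 3 samples from mice given 1 radiation dose of 5 Gy. The title of the series places the comparison within work on metabolism and the loss of salivary gland function after radiation.

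Gene counts totalled 12787135, 12722189 and 15036193 in the untreated libraries and 14454646, 7108359 and 12127162 in the irradiated ones. Between 18941 and 20219 genes had at least 1 count. Bpifa2, a secreted salivary protein, took 26.8% to 31.2% of the counts of a library, and the 10 most abundant genes together took 60.3% to 63.0%. All libraries carried the female transcript Xist at 1809 to 4129 counts, with at most 1 count in Y-linked genes. Irradiated replicate 2 had the lowest depth, and 10.01% of its reads were not aligned, against 3.75% to 4.33% in the other libraries.

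The comparison of irradiated with untreated glands asks which transcripts differ after radiation. Lists of p53 target genes, cell cycle genes, T cell markers and B cell markers were higher in irradiated glands by camera with a preset correlation, with 9 of 33, 4 of 37, 2 of 20 and 1 of 16 measured members past the threshold over all genes. With an estimated correlation none of these lists passed, at adjusted p values of 0.0948, 0.426, 0.619 and 0.619. Cdkn1a, which encodes the cell cycle inhibitor p21, rose from 2.08 ± 0.222 to 21.9 ± 3.97 CPM (SD, n = 3 each). Of the 5 most abundant genes, Bpifa2 and Amy1 had log2 fold changes of -0.08 and 0.01, and Mucl2, Smr3a and Chia1 of -0.63, -0.44 and -0.15. None of these passed the threshold. Of 12885 genes tested, 84 were higher and 45 were lower after irradiation by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The median log2 fold change of the called genes was 1.17 for rises and -0.70 for falls, with 48 rises and 7 falls beyond 2-fold. At an unadjusted p under 0.05 there were 1929 genes, where chance would give 644. Irradiated and untreated libraries did not overlap for any of the 129 called genes, nor for 21.2% of all genes, where chance gives 10%.

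The count of calls depended on the test: edgeR without robust shrinkage gave 21 higher and 5 lower, limma-voom 20 and 5, DESeq2 121 and 70, and no count filter 279 and 239. Scaling by library totals alone gave 260 higher and 22 lower, so that 92.2% of calls were higher against 65.1%, with the median of all genes shifted to 0.14 on the log2 scale. Without untreated replicate 1 the counts were 81 and 29, without untreated replicate 2 they were 56 and 21, without irradiated replicate 1 they were 31 and 14, and without irradiated replicate 3 they were 83 and 72. A correction for transcript length and GC content, chosen after seeing the data, gave 77 and 28. All 129 called genes kept their direction in each setting in which they were tested. This says little about robustness, since the groups did not overlap for any of them and a change of sign was hardly possible. Of the 39 called genes named by the rule, 10 were called in all 16 settings run on genes: Cdkn1a, Gdf15, Eda2r, Ccng1, Cxcl13, Laptm5, Retnla, Rnase1, Nupr1 and Usp2.

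**Figure D1:**
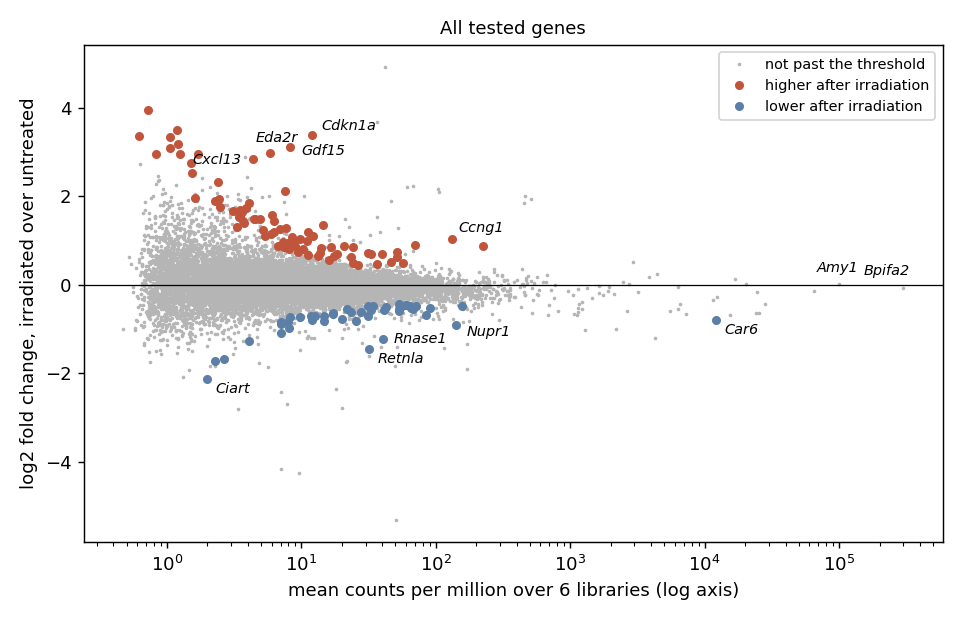
Log2 fold change of irradiated over untreated glands against mean CPM over 6 libraries (log axis) for all 12885 tested genes. Red points are the 84 genes higher and blue points the 45 genes lower after irradiation, and grey points did not pass the threshold.

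**Figure D2:**
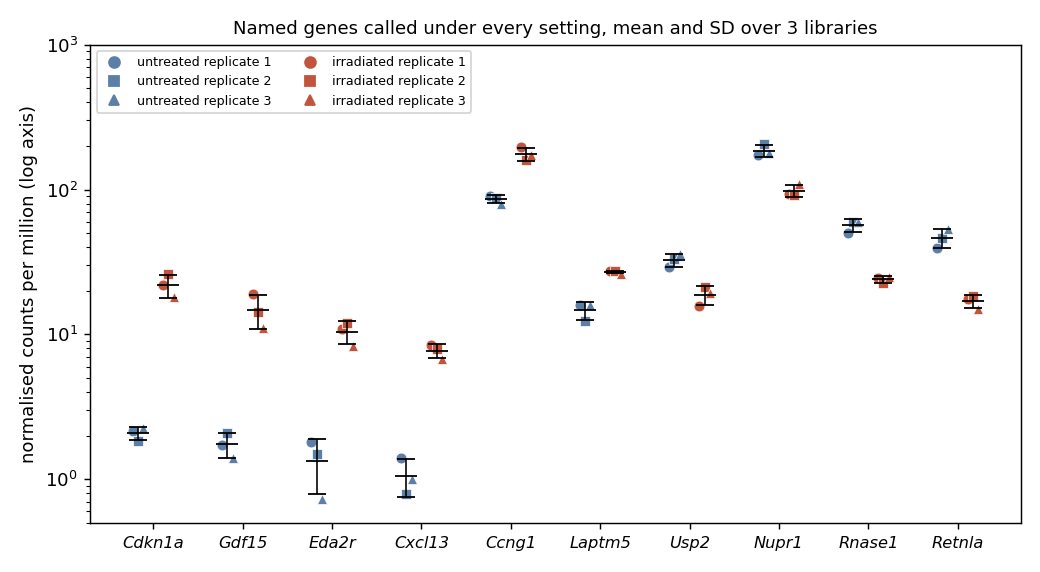
CPM on a log axis of the 10 named genes called in every setting, with 1 point per library and the mean and SD of 3 libraries as black bars. Cdkn1a stood at 2.08 CPM in untreated and 21.9 CPM in irradiated glands, and Retnla at 46.5 and 17.0 CPM.

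Of 33 measured p53 targets, 9 rose, 0 fell and 24 did not pass, and 18 rose when adjusted over the list alone. Cdkn1a (ENSMUSG00000023067; chromosome 17, 29090976 to 29100727, build mm10) had a log2 fold change of 3.38 (SE 0.19), a 10.4-fold rise, with an edgeR adjusted p of 2.03e-09. Gdf15, a secreted stress cytokine (chromosome 8, 70629393 to 70632456), rose by 3.11 (SE 0.24) on the log2 scale, from 1.74 ± 0.349 to 14.8 ± 3.98 CPM (SD, n = 3). Eda2r, a receptor of the tumour necrosis factor family (chromosome X, 97333840 to 97377216), rose by 2.97 (SE 0.28). Ccng1, which encodes cyclin G (chromosome 11, 40748552 to 40755311), rose by 1.04 (SE 0.12), from 85.8 ± 5.69 to 176.3 ± 17.8 CPM. Mdm2, the ubiquitin ligase that turns p53 over, had a log2 fold change of 0.44 (SE 0.12) and did not pass, at an edgeR adjusted p of 0.0922, though higher in each irradiated library. The other called members, Zmat3, Phlda3, Ephx1, Polk and Dglucy, were named after their values were seen, and had log2 fold changes from 0.89 to 1.35. The list's median log2 fold change was 0.89 (SE over members 0.16), with a camera adjusted p of 5.24e-16 and an adjusted p of 0.0948 with an estimated correlation. Ddias, a gene induced by DNA damage outside this list, rose by 3.34 (SE 0.62), from 1 to 3 counts in each untreated library, but its edgeR call was lost without untreated replicate 2 or irradiated replicate 1.

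Of 37 measured cell cycle genes 4 rose and 33 did not pass, 22 rose when adjusted over the list alone, and 36 had a positive fold change. Mki67, a marker of cycling cells, rose from 7.44 ± 0.847 to 14.7 ± 4.17 CPM (SD, n = 3), a log2 fold change of 0.99 (SE 0.19). Mcm5, Mcm3 and Mcm2, subunits of the replicative helicase, rose by 1.74 (SE 0.29), 1.39 (SE 0.32) and 0.86 (SE 0.20). The median of the list was 0.90 (SE over members 0.08), with a camera adjusted p of 7.36e-18 and an adjusted p of 0.426 with an estimated correlation. Mki67 and Mcm5 lost their edgeR calls without irradiated replicate 1, Mki67 also without untreated replicate 1 or 2, and Mcm3 and Mcm2 in at least 4 of the 6 sets that leave out 1 library. The medians of the T and B lymphocyte lists, 1.73 and 1.51, were higher in the same comparison, but a link between these lists and the cell cycle list was not tested. The other damage lists did not pass: the medians were 0.15 for DNA repair (camera adjusted p = 0.0913), 0.05 for apoptosis (0.346), -0.09 for senescence and its secreted factors (0.563), and 0.01 for antioxidant genes under Nrf2 (0.563). Within the last 2 of these, Igfbp7 rose by 0.47 (SE 0.11) and Sod1 fell by 0.44 (SE 0.10), both calls that 4 or more of the 6 sets leaving out 1 library removed.

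Of 20 measured T and natural killer cell markers 2 rose and 18 did not pass, and 9 rose when adjusted over the list alone. The called members were Cd5, a surface receptor of T cells, at a log2 fold change of 2.95 (SE 0.52), and Cd8b1, a chain of the CD8 coreceptor, at 2.76 (SE 0.55). Both rest on few reads, with 4, 1 and 10 counts each in the untreated libraries. The irradiated libraries held 36, 33 and 32 counts of Cd5 and 25, 30 and 32 of Cd8b1. Of 16 measured B and plasma cell markers 1 rose, Bank1, a B cell scaffold protein, by 2.32 (SE 0.45), and 3 rose when adjusted over the list alone. Fcrl1, an Fc receptor-like protein of B cells outside the list, rose by 3.10 (SE 0.66), and Cxcl13, a chemokine that attracts B cells, rose by 2.85 (SE 0.29), from 1.06 ± 0.311 to 7.72 ± 0.808 CPM (SD, n = 3). Fcrl1 had 5, 0 and 3 counts in the untreated libraries and 23, 23 and 16 in the irradiated ones. The median log2 fold changes were 1.73 (SE over members 0.18) for T cells and 1.51 (SE over members 0.325) for B cells, with camera adjusted p values of 4.31e-10 and 0.000339. The B and plasma cell list was uneven, with a mean of 0.99 and 3 of its 16 members at a negative fold change. With an estimated correlation the adjusted p was 0.619 for each.

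The untreated libraries were uneven in these markers. The T cell score, the mean log2 CPM of the members relative to the untreated mean, was -1.60 in untreated replicate 2, 0.78 and 0.82 in the other untreated libraries, and 1.71 to 2.20 in the irradiated ones. For B cells it was 1.27, -1.41 and 0.15 in untreated replicates 1, 2 and 3, and 1.32 to 1.49 in the irradiated libraries. Without untreated replicate 2 the list medians were 1.21 and 0.98, and limma-voom with all libraries gave 2.46 for B cells. Cd8b1 lost its edgeR call without untreated replicate 1, untreated replicate 2 or irradiated replicate 2, Bank1 without irradiated replicate 1, and Fcrl1 without any of untreated replicates 2 and 3 and irradiated replicates 1 and 2. Laptm5, a lysosomal protein of blood cells, rose by 0.87 (SE 0.13) as the called member among 27 macrophage and dendritic cell markers, whose median was -0.01 (camera adjusted p = 0.938). Grem1, a secreted inhibitor of bone morphogenetic proteins, rose by 3.18 (SE 0.61) and Inka2 by 2.96 (SE 0.58). Their counts in the untreated libraries were 5, 0 and 4 for Grem1 and 1, 3 and 7 for Inka2. Both lost their edgeR calls without irradiated replicate 1, and Inka2 also without untreated replicate 1 or 2.

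**Figure D3:**
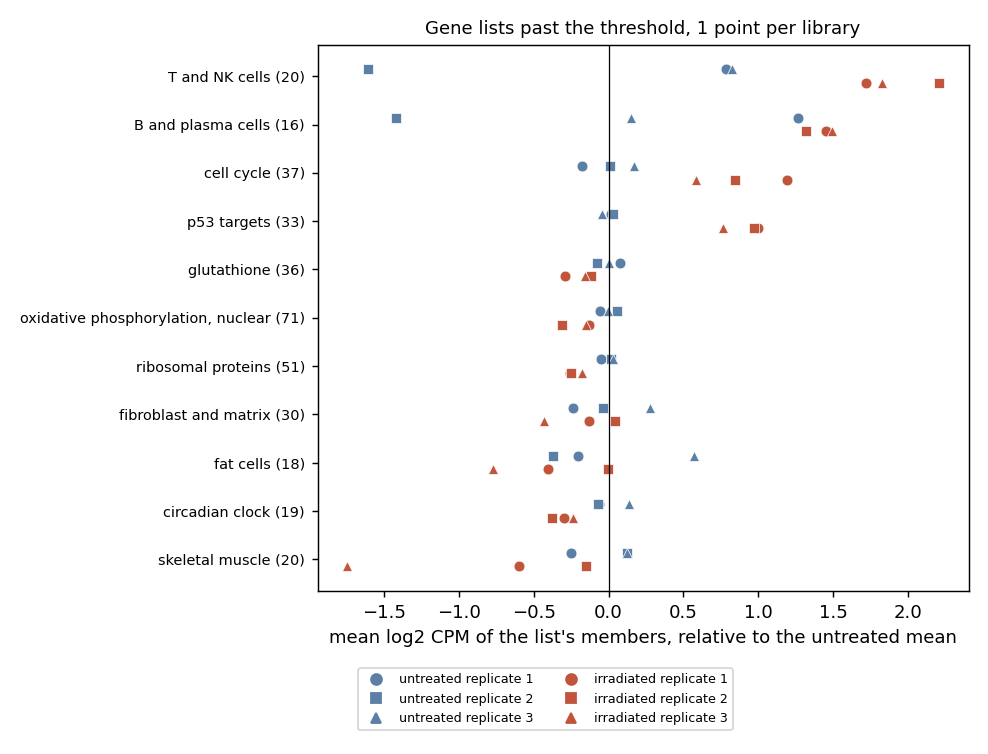
Mean log2 CPM of the members of the 11 lists past the threshold, relative to the mean of the untreated libraries, with 1 point per library and the number of measured members in brackets. The p53 score lay between 0.77 and 1.00 in the irradiated libraries and between -0.04 and 0.03 in the untreated ones, while untreated replicate 2 stood at -1.60 in the T cell score.

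Among the falls, Retnla, a secreted resistin-like protein (ENSMUSG00000061100; chromosome 16, 48842551 to 48844461), fell from 46.5 ± 6.93 to 17.0 ± 1.77 CPM (SD, n = 3). Its log2 fold change was -1.45 (SE 0.13), with an edgeR adjusted p of 2.27e-06. Rnase1, a secreted ribonuclease (chromosome 14, 51144998 to 51146785), fell from 56.6 ± 5.90 to 24.0 ± 1.23 CPM, a log2 fold change of -1.23 (SE 0.11). Nupr1, a stress-induced nuclear protein (chromosome 7, 126623249 to 126630861), fell from 185.6 ± 18.5 to 97.9 ± 9.47 CPM, a log2 fold change of -0.92 (SE 0.12). Smim22, Cyp27a1, Gal3st2b, Rsad1 and Paqr6 had log2 fold changes between -1.74 and -0.85, and each lost its edgeR call under at least 4 of the 6 sets that leave out 1 library, except Gal3st2b, which lost it under 3 of them. Smim22, Cyp27a1 and Paqr6 also lost their calls with the length and GC correction. Called falls had shorter transcripts, with a median length of 1939 bases, against 3994.5 for called rises and 3331 for all genes.

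Of 19 measured circadian clock genes 3 fell and 16 did not pass, and 8 fell and 4 rose when adjusted over the list alone. Ciart, a repressor of the clock, had a log2 fold change of -2.13 (SE 0.44), Usp2, a clock-controlled deubiquitinase, -0.82 (SE 0.13), and Tef, a transcription factor of the clock output, -0.69 (SE 0.14). The median of the list was -0.46 (SE over members 0.26), with a camera adjusted p of 0.0154 and an adjusted p of 0.426 with an estimated correlation. The list moved both ways, with 13 negative and 6 positive fold changes, so a median and a one-way test describe it poorly. Fry's adjusted p was 0.0823 for a one-way change and 0.0145 for change in either direction. The camera call was lost without untreated replicate 3, at an adjusted p of 0.0777, and the edgeR calls of Ciart and Tef were lost in 4 of the 6 sets that leave out 1 library.

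Saliva proteins held 52.0% ± 2.24 of counts in untreated and 52.4% ± 1.03 in irradiated glands (SD, n = 3). An exact two-sided permutation test of this share gave p = 0.9, where 3 against 3 libraries allow no p below 0.1. The log2 fold change was 0.01 (SE 0.17) for Amy1, salivary amylase, -0.08 (SE 0.17) for Bpifa2, 0.05 (SE 0.14) for Slc12a2, the chloride importer of fluid secretion, and -0.31 (SE 0.12) for Aqp5, the apical water channel. Among the other most abundant genes it was -0.63 (SE 0.25) for Mucl2, from 30820 ± 11320 to 19870 ± 3880 CPM (SD, n = 3), -0.44 (SE 0.17) for Smr3a, from 32460 ± 3503 to 23900 ± 4570 CPM, and -0.15 (SE 0.17) for Chia1. Lyz1, a lysozyme named after its value was seen, stood at -1.19 with an edgeR adjusted p of 0.0521. None of these passed. Smr3a and Aqp5 were lower in each irradiated library than in any untreated one, and Aqp5 stood at 233.4 ± 7.42 against 188.8 ± 18.5 CPM, with edgeR adjusted p values of 0.224 and 0.222. Car6, the secreted carbonic anhydrase of saliva, fell from 15270 ± 1091 to 8819 ± 2241 CPM (SD, n = 3), a log2 fold change of -0.79 (SE 0.18). Its edgeR adjusted p was 0.033. The call was lost in 5 of the 6 sets that leave out 1 library, and with the length and GC correction. Of 27 measured saliva proteins 1 fell and 26 did not pass, and 3 fell and 1 rose when adjusted over the list alone. The median of that list was 0.01 and the mean 0.33, while the camera test pointed lower without passing (adjusted p = 0.137).

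The remaining gland lists did not pass camera's test. The medians were -0.06 for acinar identity (adjusted p = 0.226), 0.03 for fluid secretion (0.977), -0.09 for ducts (0.238), -0.17 for basal and myoepithelial cells (0.0744), -0.08 for the unfolded protein response (0.343), and 0.01 for genes of other salivary and lacrimal glands (0.385). No member of the first 5 of these passed over all genes. Krt18, a keratin among the duct markers, stood at a log2 fold change of -0.53 (SE 0.13) with an edgeR adjusted p of 0.0541.

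Of 51 ribosomal proteins 2 fell, Rps21 by 0.52 and Rpl28 by 0.49 on the log2 scale, 49 did not pass, and 7 fell when adjusted over the list alone. The median was -0.23 (SE over members 0.02), with a camera adjusted p of 2.4e-10 and an adjusted p of 0.524 with an estimated correlation. Of 71 oxidative phosphorylation genes 1 fell, Ndufa2, a subunit of respiratory complex I, by 0.54, 70 did not pass, and 8 fell when adjusted over the list alone. The median was -0.21 (SE over members 0.02), with a camera adjusted p of 1.93e-08 and an adjusted p of 0.619 with an estimated correlation. Of 36 glutathione genes 0 passed over all genes and 4 fell when adjusted over the list alone. The median was -0.17 (SE over members 0.05), with a camera adjusted p of 0.00326 and an adjusted p of 0.395 with an estimated correlation, and without irradiated replicate 1 it was -0.11 (camera adjusted p = 0.0372). Short transcripts had lower fold changes across the whole data set: the median log2 fold change was -0.17 in the 2574 genes with the shortest transcripts and 0.10 in as many with the longest. With the correction for length and GC content the medians were -0.09 for ribosomal proteins (camera adjusted p = 0.00756), -0.06 for oxidative phosphorylation (0.223) and -0.12 for glutathione (0.104). Scaled by library totals alone, where the median of all genes was 0.14, they were -0.08, -0.06 and -0.02, each still past camera's threshold with the preset correlation. Rps21, Rpl28 and Ndufa2 lost their edgeR calls with the length and GC correction, without untreated replicate 2 or 3 and without irradiated replicate 1, Rpl28 also without untreated replicate 1, Rpl28 and Ndufa2 without irradiated replicate 2, and Ndufa2 without irradiated replicate 3.

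The other metabolic lists did not pass camera's test. The medians were -0.10 for peroxisomes (camera adjusted p = 0.0687, and fry adjusted p = 0.0169 for a one-way fall), 0.26 for sterol and bile acid genes (0.0814), 0.05 for purine and pyrimidine genes (0.184), and between -0.08 and 0.12 for lipogenesis (0.343), fatty acid oxidation (0.423), glycolysis (0.457), alanine, aspartate and glutamate metabolism (0.559), and the mitochondrially encoded subunits, serine and glycine, the citric acid cycle and polyamines (0.977 each). Cyp27a1, a mitochondrial sterol hydroxylase, fell from 9.61 ± 0.642 to 4.43 ± 1.77 CPM (SD, n = 3). When adjusted over the list alone, 7 of the 20 measured sterol and bile acid genes rose and 2 fell. Scd2, a fatty acid desaturase, rose by 0.88 (SE 0.16) and Prps2, an enzyme of nucleotide synthesis, by 0.66 (SE 0.15). The edgeR calls of Scd2 and Prps2 were lost without untreated replicate 2 or irradiated replicate 1, and that of Prps2 also without untreated replicate 3 or irradiated replicate 2.

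Markers of other cell types differed in separate ways. Of 20 skeletal muscle genes 1 fell, Tcap, which anchors titin, at a log2 fold change of -1.27 (SE 0.28). Their median was -0.68 (SE over members 0.06), with a camera adjusted p of 4.22e-07 and an adjusted p of 0.619 with an estimated correlation. The muscle score was -1.74 in irradiated replicate 3, -0.60 and -0.15 in the other irradiated libraries and -0.25 to 0.13 in the untreated ones, and the median was -0.34 without irradiated replicate 3 and -1.06 without irradiated replicate 2. Tcap lost its edgeR call without untreated replicate 1 or 3 or irradiated replicate 1 or 3, and with the length and GC correction. Fat cell genes had a median of -0.36 with 0 of 18 called (camera adjusted p = 0.01, and adjusted p = 0.768 with an estimated correlation). That call was lost without untreated replicate 3, where the median was 0.01, or without irradiated replicate 3, where it was -0.22, and library totals alone gave -0.21. Fibroblast and matrix genes had a median of -0.25 with 1 of 30 called, Pi16, a secreted protease inhibitor, which fell by 0.62 (camera adjusted p = 0.0363, and adjusted p = 0.776 with an estimated correlation). The list call was lost without the same libraries, at medians of -0.09 and -0.11, while the median was -0.37 without untreated replicate 1 and -0.09 by library totals alone, and the edgeR call of Pi16 without untreated replicate 2 or 3 or irradiated replicate 1 or 2. Lists of endothelial (median 0.13), nerve and Schwann (-0.05), red blood (-0.62), neutrophil and mast (-0.49) and thermogenic fat cells (-0.12), interferon response (0.11) and immediate early genes (0.11) did not pass, with camera adjusted p values of at least 0.0913.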

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

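The tests of the lymphocyte and clock patterns and the correction for length and GC content were chosen only after the results were seen.

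In data outside the gene counts, 3 read categories stood above the untreated libraries by more than the untreated range. Reads not aligned made up 10.01% of irradiated replicate 2, against 3.98% to 4.33% in the untreated libraries. Reads aligned to more than 1 place made up 18.4% of the same library, against 13.6% to 16.0%. Reads overlapping more than 1 gene made up 9.83% of irradiated replicate 1, against 8.88% to 9.23%. The quality category of irradiated replicate 2 held 184 reads, where the other libraries had 342749 to 491591.

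The ribosomal protein and oxidative phosphorylation lists were lower after irradiation, by a median of -0.23 and -0.21 with camera's preset correlation, and neither passed with an estimated one (adjusted p = 0.524 and 0.619). Different processing of irradiated replicate 2 is argued against as the source, since without it the medians were -0.23 (camera adjusted p = 3.69e-08) and -0.157 (0.000473), and both other irradiated libraries scored below every untreated one for each list. A trend with transcript length and GC content remains open: among 10000 lists matched on length, GC content and level, the medians stood at percentiles 4.37 and 5.25, and the matched lists had medians of -0.16 each. Correcting for both left -0.09 for ribosomal proteins, still past the threshold, and -0.06 for oxidative phosphorylation, no longer past it because the fold change shrank. Such a trend could come from RNA quality or library preparation, or from biology. It was measured only as a difference between the groups, not in each library.

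B and T lymphocyte lists were higher after irradiation with camera's preset correlation, and neither passed with an estimated one (adjusted p = 0.619 for each). A lower share of the main cell type as the only source is argued against by 6 lists of other cell types. Their medians were already known when this test was chosen. The highest was 0.13, for endothelial cells, and that of macrophages and dendritic cells was -0.01. The muscle, fat and fibroblast medians say less, since they moved with single libraries. The lymphocyte medians were 1.73 and 1.51, and the mean of the B cell list was 0.99. The bound used was 1.19, the B cell median less the SE over members, which takes genes as independent and is not an error of the median. For T cells, untreated replicate 2 as the only source is argued against. Without it the lowest irradiated score lay 0.893 above the highest untreated one, against an SD of 0.257 within the irradiated group. Variation between samples stays open, since few untreated libraries were left and the untreated scores ran from -1.60 to 0.82. The list also did not pass with an estimated correlation (camera adjusted p = 0.485). For B cells untreated replicate 2 as the only source stays open, since the gap was 0.052. Untreated replicate 1 stood at 1.27 against 1.32 to 1.49 in the irradiated libraries, and camera's adjusted p with an estimated correlation was 0.751. Lymphoid tissue taken along at dissection cannot be told apart from an influx of lymphocytes, since both bring the same markers: the exact two-sided permutation p of the mean B and T score, 0.1, is the smallest that 3 against 3 allow and decides nothing.

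Clock genes that peak with Arntl had a median log2 fold change of 1.37 over 4 measured genes, of which 0 passed edgeR's test, and 11 output genes had a median of -0.82, of which 3 passed. The difference of 2.19 is consistent with tissue taken at another time of day. A stress or glucocorticoid response remains open: the immediate early and glucocorticoid list had a median of 0.11, but its members went both ways (SD 0.56), and its score was 0.27, 0.42 and -0.28 in the irradiated libraries. An effect of radiation on the clock also remains open, and collection times were not given in the sources used here.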

How the results depend on the processing

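The correction for transcript length and GC content was chosen after seeing the data, and all other alternatives before the data were examined. The 129 called genes kept their direction in every setting in which they were tested, which was largely fixed beforehand, since the groups did not overlap for any of them. Of the 39 named genes called, 10 kept their call in all settings other than leaving out a library, and 11 in all 6 sets leaving out 1 library. Of 11 called lists, 8 kept their call in those 6 sets and 0 in all other settings, since the estimated correlation removed each one. Genes higher and lower numbered 260 and 22 by library totals only, 279 and 239 with no count filter, 21 and 5 without robust shrinkage, and 20 and 5 by limma-voom. DESeq2 gave 70 lower, and the length and GC offset 28 lower. Lists higher numbered 7 with no count filter. Lists higher and lower numbered 0 and 0 by camera with an estimated correlation, and 1 and 2 by fry. Leaving out 1 library gave 31 to 83 genes higher, 14 to 72 lower, 4 to 7 lists higher and 5 to 11 lower. With no filter 25422 genes were tested, and leaving out a library leaves fewer samples; elsewhere the cause was not tested. With the replicate block, 39 genes were higher and 14 lower, 43 of them among the 129. Same-numbered libraries of both groups deviated from their group means with correlations of 0.02, -0.111 and -0.107, so the numbers were not taken as pairs. DESeq2 and the lack of robust shrinkage have no list test. At this depth 8.06% of simulated 1.5-fold changes were called, so smaller changes are mostly out of reach for single genes.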

Other observations

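The genes named here, and the test of reads assigned to no feature, were chosen after their values were seen. Of the 129 called genes, 97 belonged to no fixed list. Some of these are given here as single genes, with no test of a common theme. Cd69, an early activation marker of lymphocytes, had 1 count in each untreated library and 15, 10 and 22 in the irradiated ones. Ikzf1, a transcription factor of lymphocyte development, had a log2 fold change of 2.11, Irf8, a factor of B cells and dendritic cells, 1.57, Itgal, an integrin chain of white blood cells, 1.48, and Vcam1, the adhesion molecule that binds white blood cells to vessel walls, 1.15. The G1 cyclins Ccnd1 and Ccnd2 rose by 0.74 and 0.66. Among the falls were Klf9, a glucocorticoid-induced transcription factor (-0.48), Eif4ebp1, a repressor of translation initiation (-0.54), and Adh1, an alcohol dehydrogenase (-0.52).

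Obp1a, an odorant-binding protein, stood at 39629 CPM in untreated replicate 1 and between 15467 and 28343 CPM in the other libraries. Igha and Jchain, markers of plasma cells, had log2 fold changes of -1.76 and -1.38, opposite in sign to the median of the B and plasma cell list, with edgeR adjusted p values of 0.612 and 0.687.

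Arntl stood at 0.411, 1.05 and 0.267 CPM in the untreated libraries and at 3.13, 4.81 and 1.21 CPM in the irradiated ones, a log2 fold change of 2.41 (SE 0.57) with an edgeR adjusted p of 0.054. Dbp, a D-box output gene, stood at 36.2, 24.4 and 39.0 CPM and at 6.33, 4.21 and 19.0 CPM. Irradiated replicate 3 lay nearest to the untreated libraries for both.

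Reads that the counting assigned to no feature made up 5.47% ± 0.329 of reads in untreated and 4.24% ± 0.259 in irradiated libraries (SD, n = 3). The groups did not overlap, and an exact two-sided permutation p was 0.1, the smallest that this design allows. This category need not mean reads outside genes, since the strand setting of the counting was not given.

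For several lists that did not pass, the signs of the median, the mean and the camera test differed. These were saliva proteins, other salivary and lacrimal glands, mitochondrially encoded subunits, senescence, macrophages, fluid secretion, polyamines, thermogenic fat, the citric acid cycle and the Nrf2 genes. For the mitochondrially encoded subunits the median was -0.02 and the mean 0.85.

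The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 129 genes, as 1 of the 10 splits did, itself included, and the highest other split gave 3. For gene lists the real split gave 11, 4 of the 10 splits gave as many, itself included, and the highest other split gave 15, the one that sets untreated replicates 1 and 2 and irradiated replicate 3 against the rest.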
